A study of Oryza sativa Japonica Group with 12 samples.

How the data were processed

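Total RNA from stem bases was labelled with biotin as cRNA and hybridised to 1-colour Affymetrix arrays, 1 array for each of the 12 samples, per the labels' protocols. The deposited values were on the log2 scale after RMA, the only tool named in the submitters' processing notes; its version, the genome build and the annotation behind the probe sets are not given in the sources used here. RMA corrects the background, makes the distributions of the arrays alike and summarises the probes of each probe set, so differences in total RNA between arrays cannot be seen in these values, and differences of weakly expressed genes are compressed. No further scaling was applied before the tests. Signal over background is not part of the deposited values and was not used here.

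The table held 36643 probe sets. The platform annotation paired 24251 of them with at least 1 gene, 24161 with 1 gene and 90 with several, and 12392 were unnamed in it. Control probe sets were to be left out, and they could not be told from other unnamed probe sets, so the tests ran on the 24251 annotated probe sets. Names came from the gene table of assembly ASM3414082v1, in which all 24160 genes measured by a single-gene probe set had a record and 2731 an informative name. The build used to design the array was not stated, so no coordinates are given and the gene table served for names and gene order only. The 1 gene with 2 probe sets was represented by the brighter one. OsbHLH044 and CRL1, which were to be reported first, matched no name among the tested probe sets.

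The samples were grouped by the line names in the labels, which also give the couple. A linear model with the 4 line means was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 8 residual degrees of freedom), so that all lines share an estimate of the spread. The contrasts were the mean of both couples, each couple, the difference between the couples, and null 67.1 minus null 67.5; tests were two-sided, with Benjamini-Hochberg adjustment over the tested probe sets and a threshold of 0.05. The median SE was 0.0773 for the mean of both couples, 0.109 for each couple and 0.155 for the difference between them. An exact permutation test of 3 arrays against 3 cannot go below p = 0.1, so single genes were tested only in the model. The labels say that the experiment was repeated independently 3 times and do not say whether equal repetition numbers mark a shared day. The main fit left the repetition number out, and a fit with it as a block was an alternative. The SEs and p-values rest on the spread between arrays within lines, so they cannot separate the transgene from other differences between sister lines.

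Gene lists were tested with camera and a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 33 lists of a contrast that had at least 5 measured members, and again with the correlation estimated from the data. The themes of 30 of the 34 lists, the comparisons, the rule for named genes and most alternatives were fixed before the data were examined. The lists had been meant to be matched on gene descriptions, which the tables do not hold; name patterns were therefore written after the annotation and a first fit had been seen, and before any list was tested. At that point 4 lists were added: calcium sensors and kinases, sugar transport and sucrose or trehalose metabolism, ER chaperones and protein disulfide isomerases, and homeobox genes. The lists hold 1204 genes in all, and since only named genes could enter, each covers part of its theme.

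The rule for named genes took, on the mean of both couples, up to 10 informatively named genes in each direction that passed and whose arrays were separated in both couples. For each couple, the difference between couples and the null lines it took up to 5 in each direction. For each list it took up to 2 passing members in each direction, or the member with the smallest p where none passed. For the difference between couples and the null lines, unnamed genes entered too. Genes outside this rule that the text gives as examples of lists, among them NAS1, SAG12, TPP8, TPP1, SWEET4, Lsi1, Lsi6, HSP17.9A, ORC4, PSAH and AMY1.4, were chosen after their values were seen, as were the unnamed genes given for the mean of both couples and for each couple, LOC4331887 included.

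The fit was tested on simulated data with 24251 probe sets, of which 100 were changed by 0.5 and 100 by 1 on the log2 scale. For the mean of both couples it recovered 94% of the changes of 0.5 and 100% of those of 1, with 9 false calls among 203. For couple 67.1 the shares were 52% and 100%, for couple 67.5 they were 55% and 100%, for the difference between couples 11% and 93%, and for the null lines 53% and 100%. In the same kind of simulation for the mean of both couples, camera recovered 10 of 10 shifted lists of 30 genes with no false list. The simulated genes varied independently of each other. The absence of false lists therefore does not carry over to lists whose genes are correlated. The simulated arrays also shared no deviation by replicate number, so the recovered shares and false calls may not carry over to the real arrays.

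The alternatives were the replicate number as a block, a filter on low values, a second quantile normalization, median centring, eBayes with a trend and robust estimation, array weights, a threshold that also asks for a log2 difference of at least 1, the 6 arrays of a couple alone, 6 against 6 arrays with the couple as a covariate, the mean of a gene's probe sets, and leaving out each array in turn. Chosen after seeing the data were the test over all probe sets, leaving out the arrays at both ends of the first principal component, the list tests after other scalings and without single arrays, and the comparison of the lines of couple 67.1 with those of couple 67.5. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.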

Results

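Gene expression was measured in the stem bases of 6-day-old rice plantlets, the region from which crown roots emerge. All plants belonged to the crl1 mutant of the japonica cultivar Taichung 65; this mutant lacks crown roots. A pair of transgenic lines overexpressed the transcription factor gene OsbHLH044. Each was set against its own null segregant sister line, which had lost the transgene. The couples are named here by the first part of their line names, 67.1 and 67.5, and the lines are named OE 67.1, null 67.1, OE 67.5 and null 67.5. Each line had 3 arrays, each from an independent repetition in which several stem bases were pooled, so the 12 arrays made 4 groups of 3. The medians of the 12 arrays over all probe sets lay between 4.34 and 4.39 on the log2 scale, and the number of arrays limits the precision. The levels of OsbHLH044 and of CRL1, the gene mutated in the background of all lines, are not reported here, because no tested probe set carried either name in the annotation used.

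In order to find the genes that changed with OsbHLH044 overexpression, the overexpressing lines were first compared with their null sisters as the mean of both couples. Among the probe sets paired with a gene, the largest rise was that of LOC4331887, a gene without an informative name, by 3.31 ± 0.08 (log2 difference ± SE, adjusted p = 6.86e-12). Its level was 6.30 ± 0.19 (SD, n = 3) in null 67.1 against 9.68 ± 0.07 in OE 67.1, and 6.25 ± 0.20 in null 67.5 against 9.50 ± 0.08 in OE 67.5. The genes that fell included TIP1;2 (LOC4324303), which encodes a tonoplast aquaporin, with a difference of -1.79 ± 0.16 (adjusted p = 1.34e-04), and ICL (LOC4343441), the isocitrate lyase of the glyoxylate cycle, with -1.38 ± 0.08 (adjusted p = 2.84e-07). CML1 (LOC4327351), a calmodulin-like protein gene, fell by 1.12 ± 0.15 (adjusted p = 0.00721). Among genes of the cell wall, the beta-expansin gene EXPB15 (LOC4336601) rose by 1.05 ± 0.18 and the endoglucanase gene GLU15 (LOC4345463) rose by 0.73 ± 0.13. In couple 67.1 by itself EXPB15 differed by 0.664 ± 0.249 and GLU15 by 0.285 ± 0.186. Neither passed there, and the overexpressing and null arrays of both genes overlapped. EXPB15 kept its call only without null 67.1 replicate 1 or 2, null 67.5 replicate 3 or OE 67.5 replicate 1. GLU15 kept it only without null 67.1 replicate 2, OE 67.1 replicate 1 or OE 67.5 replicate 1, and the other calls of this paragraph held without each array in turn.

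In all, 45 of the 24251 tested probe sets passed the threshold, of which 15 were higher and 30 lower in the overexpressing lines. Of these 45, 6 differed by at least 1 on the log2 scale and 43 had the same sign in both couples. By themselves, 35 also passed in couple 67.5 and 3 in couple 67.1. The difference between the couples had an unadjusted p under 0.05 in limma for 27. In 29 of the 45 the arrays of the overexpressing line all lay on 1 side of the arrays of the null line in both couples. Without selection 3 arrays separate from 3 by chance in 10% of genes within a couple. These probe sets were selected for their difference, which favours separated arrays and equal signs, so this share is no test of them. Further named genes that fell were PDX12 (LOC4347937), of vitamin B6 synthesis, with -0.85 ± 0.15, and the nucleoredoxin gene Nrx1-1 (LOC4333075) with -0.75 ± 0.09. The nicotianamine synthase gene NAS3 (LOC4344361) differed by -0.60 ± 0.11, the h-type thioredoxin gene TRXH (LOC4342593) by -0.55 ± 0.09 and the hexokinase gene HXK4, also listed as HXK8 (LOC4326776), by -0.34 ± 0.06. Chosen after their values were seen, 3 unnamed genes with large falls were LOC9266183 (-1.05 ± 0.15), LOC4344595 (-0.95 ± 0.17) and LOC4349329 (-0.93 ± 0.12). The calls of Nrx1-1, LOC9266183 and LOC4349329 held without each of the 12 arrays in turn. The call of HXK4 was lost without any 1 array (highest adjusted p = 0.107). PDX12 kept its call only without null 67.1 replicate 2 or null 67.5 replicate 2. NAS3 kept it only without null 67.1 replicate 1 or OE 67.1 replicate 3, and LOC4344595 only without null 67.5 replicate 1 or 2. TRXH kept it only without null 67.1 replicate 1 or null 67.5 replicate 2 or 3. The total of 45 probe sets fell to between 14, without OE 67.5 replicate 2, and 26, without null 67.1 replicate 3, when any array other than null 67.5 replicate 2 or 3 was left out. With all 36643 probe sets of the array in the test, 15 of the 45 kept their call, and after a further quantile normalization 14 probe sets were higher and 48 lower.

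**Figure D1:**
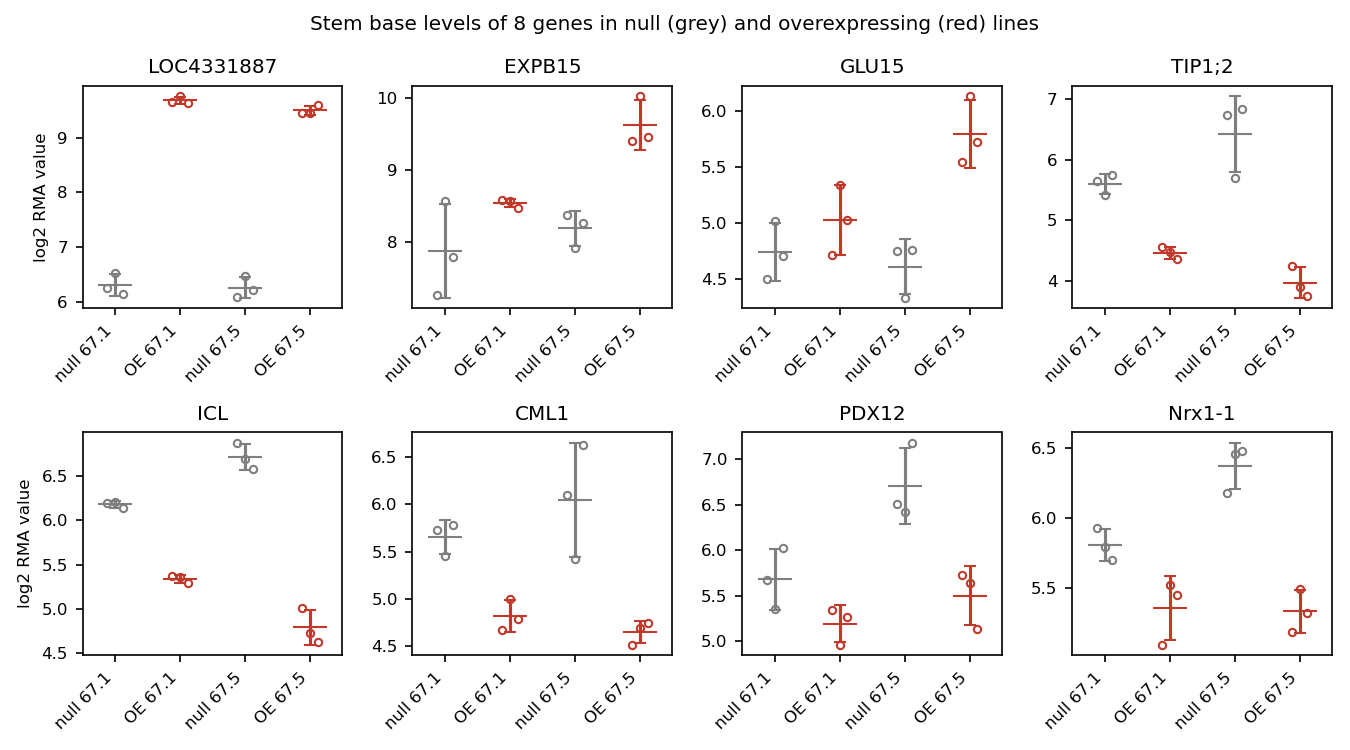
Log2 RMA values of 8 genes on each of the 12 arrays, by line (grey, null lines; red, overexpressing lines; circles, single arrays; horizontal bars and whiskers, mean and SD of 3 arrays). LOC4331887 had means of 6.30 and 6.25 in the null lines and of 9.68 and 9.50 in the overexpressing lines. ICL (LOC4343441) differed by -0.84 in couple 67.1 and by -1.92 in couple 67.5.

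Gene lists were tested on the mean of both couples with camera, which compares the members of a list with all other genes, and 7 of 33 lists passed, 1 higher and 6 lower. Without OE 67.1 replicate 1 the number that passed was 11, and with the replicate number as a block it was 8, with 2 higher and 6 lower. Among 100 splits of the arrays within the couples, the real one included, 8 gave at least 7 lists. The list of mineral uptake transporters and aquaporins, which serve as root markers, was lower in the overexpressing lines, with 61 of 78 members lower (adjusted p = 7.29e-06, and adjusted p = 0.12 with an estimated correlation). Only TIP1;2 in this list passed over all genes, and the same count of 1 passed when adjusted over the list alone; the silicon channel genes Lsi1 (LOC4330713) and Lsi6 (LOC4340558) differed by -0.24 ± 0.07 and -0.27 ± 0.08 without passing. Of the 37 genes of iron homeostasis 25 were lower (adjusted p = 0.0151, and adjusted p = 0.378 with an estimated correlation), a call that was lost without OE 67.1 replicate 3 (adjusted p = 0.0879). NAS3 was the 1 member that fell over all genes, as when adjusted over the list alone, while NAS1 (LOC4332608), another nicotianamine synthase gene, differed by -1.51 ± 0.43 (adjusted p = 0.269). The list of heat shock proteins and factors had 34 of 49 members lower (adjusted p = 6.85e-04, and adjusted p = 0.12 with an estimated correlation). None of its members passed over all genes and 4 were lower when adjusted over the list alone, with differences of -0.34 ± 0.08 for the heat stress factor gene HSFB2C (LOC4347637) and -0.37 ± 0.09 for HSP17.9A (LOC4332357). HSFB2C lay at 2.76 to 3.7 on all arrays, below the median of every array. In couple 67.1 its overexpressing and null arrays overlapped. In couple 67.1 by itself 26 of 49 heat shock members (adjusted p = 0.834), 20 of 37 iron members (adjusted p = 0.901) and 43 of 78 transporter members (adjusted p = 0.0793) were lower, and none of these lists passed. The change differed between the couples in each of them (adjusted p = 0.00136, 0.0279 and 0.0279, and adjusted p = 0.315, 0.49 and 0.539 with an estimated correlation).

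The list of cell cycle and DNA replication genes was the 1 list that was higher, with 87 of 109 members higher by a mean of 0.07 (adjusted p = 4.11e-05, and adjusted p = 0.565 with an estimated correlation). No member passed over all genes or adjusted over the list alone; POLD1 (LOC4349968), a catalytic subunit of DNA polymerase delta, differed by 0.29 ± 0.08 and ORC4 (LOC4324139), of the origin recognition complex, by 0.28 ± 0.08. Cytochrome P450 genes were lower in 30 of 37 cases (adjusted p = 0.00222, and adjusted p = 0.0972 with an estimated correlation), with CYP701A9 (LOC4341340) at -0.20 ± 0.06 and no member past the threshold, adjusted over the list alone included. Of 59 genes of sugar transport and of sucrose or trehalose metabolism 35 were lower (adjusted p = 0.0255, and adjusted p = 0.228 with an estimated correlation). This call was lost without null 67.1 replicate 3 (adjusted p = 0.0608) or OE 67.1 replicate 2 (0.0728). HXK4 fell over all genes, and 6 members passed when adjusted over the list alone, 5 lower and 1 higher. Among the lower ones were the trehalose phosphatase gene TPP8 (LOC4340524, -0.61 ± 0.12) and the sugar transporter gene SWEET4 (LOC4329093, -0.34 ± 0.07). The higher one was TPP1 (LOC4330221, 0.29 ± 0.08), another trehalose phosphatase gene. Photosynthesis genes, used as markers of green tissue, were lower in 15 of 19 cases (adjusted p = 0.0151, and adjusted p = 0.565 with an estimated correlation), without a passing member over all genes or adjusted over the list alone; PSAH (LOC4339593) differed by -0.28 ± 0.11 and RCABP69 (LOC4343583) by -0.17 ± 0.07. The photosynthesis list did not pass without null 67.1 replicate 3 (adjusted p = 0.133), OE 67.1 replicate 2 (0.0805) or null 67.5 replicate 3 (0.154). In couple 67.1 by itself 14 of 19 photosynthesis members (adjusted p = 0.765), 25 of 37 cytochrome P450 members (0.315) and 35 of 59 sugar members (0.0793) were lower and 79 of 109 cell cycle members higher (0.0793), and none of these lists passed.

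The other 26 lists did not pass on the mean of both couples. In the list of cell death, autophagy and senescence, 15 of 31 members were lower (adjusted p = 0.446). None passed over all genes and 2 were lower when adjusted over the list alone. These were the cysteine protease gene SAG12, also listed as EP3A and REP1 (LOC4324982, -1.04 ± 0.21), and LOL4 (LOC4344587, -0.46 ± 0.09). Crown root regulators had 8 of 15 members lower (adjusted p = 0.571), with SCR1 (LOC4349638) at 0.26 ± 0.11. For hormone lists the adjusted p was 0.931 for auxin (74 genes, GH3.1, LOC4327043, -0.20 ± 0.07), 0.3 for cytokinin (43 genes, CKX11, LOC4345764, -0.21 ± 0.08), 0.931 for ethylene (11 genes, ACO1, LOC4347225, -0.13 ± 0.06) and 0.79 for jasmonate (38 genes, JAZ3, LOC4345625, 0.25 ± 0.06). It was 0.829 for abscisic acid and dehydration (88 genes, P5CS2, LOC4324853, 0.22 ± 0.07) and 0.718 for gibberellin (16 genes, KAO, LOC4339885, -0.15 ± 0.07). No member of the crown root list or of these hormone lists passed, either over all genes or adjusted over the list alone.

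Among lists of defence and stress, pathogenesis-related proteins had 12 of 16 members lower (adjusted p = 0.0721), and Cht6 (LOC4329920, -0.22 ± 0.06) was the 1 member that passed when adjusted over the list alone. The level of Cht6 (2.99 to 3.37) lay below the median of every array. Diterpenoid phytoalexin synthesis had an adjusted p of 0.232 (19 genes, CYP76M7, LOC4341447, -0.21 ± 0.07), WRKY factors 0.829 (6 genes, WRKY9, LOC4343736, 0.17 ± 0.08), lectin and cysteine-rich receptor kinases 0.79 (5 genes, CRK6, LOC4343500, -0.14 ± 0.07) and antioxidant enzymes with glutathione transferases 0.12 (52 genes, GRXC6, LOC4336354, -0.27 ± 0.07). For low oxygen and fermentation it was 0.64 (7 genes, Adh2, LOC4350054, 0.33 ± 0.12). Calcium sensors and kinases had 53 of 90 members lower (adjusted p = 0.311), with CML1 past the threshold over all genes and 2 lower when adjusted over the list alone. The adjusted p was 0.931 for ER chaperones and protein disulfide isomerases (27 genes, ERDJ3A, LOC4332515, -0.25 ± 0.09). No member of the diterpenoid, WRKY, receptor kinase, antioxidant, low oxygen or ER chaperone lists passed over all genes or adjusted over the list alone.

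Cell wall remodelling genes had 64 of 114 members lower (adjusted p = 0.931), a median of -0.01 and a mean of 0.02, and the 2 that passed, over all genes and adjusted over the list alone, were EXPB15 and GLU15, which rose. Cytosolic ribosomal proteins were higher in 19 of 21 cases (adjusted p = 0.0595, RPL11, LOC4338077, 0.20 ± 0.09), and histones in 9 of 10 (adjusted p = 0.352, H2B.10, LOC4324495, 0.19 ± 0.10). Markers of seed tissue had 9 of 15 members lower (adjusted p = 0.0536), and 2 alpha-amylase genes were lower when adjusted over the list alone, AMY1.1 (LOC4330832, -0.60 ± 0.12) and AMY1.4 (LOC4345812, -0.25 ± 0.08). The levels of AMY1.1 (2.1 to 3.26) and AMY1.4 (2.98 to 3.6) lay below the median of every array. Phenylpropanoid and lignin genes had an adjusted p of 0.311 (44 genes, ROMT-15, LOC4345934, -0.18 ± 0.06). Among other transcription factors it was 0.718 for bHLH (19 genes, RAI1, LOC4331538, -0.23 ± 0.08), 0.79 for NAC (10 genes, NAC048, LOC4325006, -0.20 ± 0.11), 0.311 for MYB (11 genes, MYBAS1, LOC4351184, -0.18 ± 0.08), 0.931 for AP2/ERF (18 genes, DREB2B, LOC4338484, 0.27 ± 0.10) and 0.3 for homeobox genes (50 genes, Hox19, LOC4332147, -0.37 ± 0.09). The class III peroxidase list had 4 measured members and was not tested; PRX112 differed by -0.17 ± 0.12. No member of the ribosomal, histone, phenylpropanoid or transcription factor lists named here passed over all genes or adjusted over the list alone.

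Within couple 67.1, 4 probe sets passed, 3 higher and 1 lower in the overexpressing line. LOC4331887 rose by 3.38 ± 0.11 (adjusted p = 7.03e-10) and, chosen after their values were seen, the unnamed genes LOC9267697 and LOC4343264 rose by 1.94 ± 0.28 and 1.31 ± 0.14 (adjusted p = 0.0381 and 0.00269). ICL fell by 0.84 ± 0.11, from 6.18 ± 0.04 (SD, n = 3) in the null line to 5.34 ± 0.05 (adjusted p = 0.0112). TIP1;2 (-1.14 ± 0.23) and CML1 (-0.83 ± 0.22) had all 3 overexpressing arrays below all null arrays of this couple without passing (adjusted p = 0.243 and 0.689). None of the 33 lists passed; at an unadjusted p under 0.05, limma gave 840 probe sets, 3.46% of those tested. The ICL call was lost without null 67.1 replicate 1 or 2 or any OE 67.1 array (highest adjusted p = 0.115), and the call of LOC9267697 without 7 of the 12 arrays, all but OE 67.1 replicate 3, null 67.5 replicate 1 or 3 and OE 67.5 replicate 1 or 2. The count of couple 67.1 was 2 without null 67.1 replicate 1, null 67.1 replicate 2 or OE 67.1 replicate 1. After a further quantile normalization it was 7, of which 4 were higher and 3 lower.

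Within couple 67.5, 83 probe sets passed, 25 higher and 58 lower in the overexpressing line. TIP1;2 (LOC4324303) fell by 2.45 ± 0.23, from 6.42 ± 0.62 (SD, n = 3) to 3.96 ± 0.26 (adjusted p = 1.55e-04). Further falls were those of ICL (LOC4343441, -1.92 ± 0.11, adjusted p = 3.55e-07), CML1 (LOC4327351, -1.41 ± 0.22), PDX12 (LOC4347937, -1.21 ± 0.21) and Nrx1-1 (LOC4333075, -1.04 ± 0.13). The rises included LOC4331887 by 3.24 ± 0.11, EXPB15 (LOC4336601) by 1.44 ± 0.25 and GLU15 (LOC4345463) by 1.18 ± 0.19. PRR1 (LOC4330000), a pseudo-response regulator gene, rose by 0.73 ± 0.12 and GRF3 (LOC4336879) by 0.56 ± 0.10. Chosen after their values were seen, the further genes that fell were LOC4331301 (-2.33 ± 0.39), LOC9267697 (-1.63 ± 0.28), HSFB2C (LOC4347637, -0.70 ± 0.12) and YSL2 (LOC4330161, -0.53 ± 0.10), a gene for a transporter of metal complexes with nicotianamine. YSL2 lay at 3.4 to 4.33 over all arrays, below the median of every array. LOC9272344 rose by 1.54 ± 0.14 and LOC4329504 by 1.36 ± 0.10. In 75 of the 83 probe sets (90.4%) null 67.1 differed from null 67.5 in the same direction as OE 67.5 did, by a median 0.478 of the change in couple 67.5. Both differences share null 67.5, and in 50 simulations in which OE 67.5 alone changed the highest values were 68.4% and 0.0562. In these simulations each gene varied on its own, so the values are no bounds for genes that deviate together. The count of 83 in couple 67.5 fell to 20 without OE 67.5 replicate 3, 25 without OE 67.5 replicate 2, 29 without OE 67.5 replicate 1, 43 without null 67.5 replicate 3 and 51 without null 67.5 replicate 1; with all 36643 probe sets in the test, 20 of the 83 kept their call. The calls of LOC4331887, TIP1;2, ICL, Nrx1-1, LOC9272344 and LOC4329504 held without each of the 12 arrays in turn. EXPB15 lost its call without any array of couple 67.5, CML1 without any OE 67.5 array, GLU15 without OE 67.5 replicate 2 or 3, and PRR1 without these or null 67.5 replicate 1. GRF3 lost it without null 67.1 replicate 1 or any array of couple 67.5 except null 67.5 replicate 2, PDX12 without any array of couple 67.5 except null 67.5 replicate 2, and LOC4331301 and LOC9267697 without null 67.5 replicate 3 or any OE 67.5 array. HSFB2C lost it without null 67.5 replicate 1 or 3 or OE 67.5 replicate 2 or 3, and YSL2 without any array except null 67.1 replicate 1 and OE 67.1 replicates 2 and 3.

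In this couple 9 of 33 lists passed, of which cell cycle and DNA replication was higher (85 of 109 members, adjusted p = 9.19e-05, and adjusted p = 0.501 with an estimated correlation) and 8 were lower. Heat shock proteins and factors had 36 of 49 members lower (adjusted p = 1.8e-05, and adjusted p = 0.0629 with an estimated correlation), and mineral uptake transporters with aquaporins 60 of 78 (adjusted p = 1.53e-05, and adjusted p = 0.138 with an estimated correlation). Iron homeostasis had 27 of 37 members lower (adjusted p = 0.00182, and adjusted p = 0.214 with an estimated correlation); TIP1;2 and YSL2 were the members of the transporter and iron lists that fell, and 3 of each were lower when adjusted over the list alone. Of the heat shock list HSFB2C fell and 4 were lower when adjusted over the list alone. In the cell cycle list 1 gene was higher when adjusted over the list alone, and in the other lists that passed no member was. Cytochrome P450 genes had 32 of 37 members lower (adjusted p = 0.00182, and adjusted p = 0.0629 with an estimated correlation) and photosynthesis genes 15 of 19 (adjusted p = 0.00343, and adjusted p = 0.501 with an estimated correlation). The photosynthesis list was also lower in null 67.1 than in null 67.5 (17 of 19 members, adjusted p = 0.00136, and adjusted p = 0.634 with an estimated correlation), and the mean of its member RCABP69 (LOC4343583) was 9.72 in null 67.5 and 9.41 to 9.44 in the other lines. Phenylpropanoid and lignin genes were lower in 31 of 44 cases (adjusted p = 0.0123, and adjusted p = 0.347 with an estimated correlation), diterpenoid phytoalexin genes in 18 of 19 (adjusted p = 0.0243, and adjusted p = 0.501 with an estimated correlation) and pathogenesis-related proteins in 12 of 16 (adjusted p = 0.0376, and adjusted p = 0.407 with an estimated correlation). The diterpenoid and pathogenesis-related calls were lost after a further quantile normalization (adjusted p = 0.127 and 0.0772). Without null 67.5 replicate 1 the adjusted p was 0.145 for diterpenoid genes, 0.145 for phenylpropanoid genes and 0.304 for pathogenesis-related proteins, and without null 67.5 replicate 3 it was 0.133 for photosynthesis genes and 0.0994 for pathogenesis-related proteins. The pathogenesis-related call was also lost without OE 67.5 replicate 1 (0.0602) or 3 (0.162), and the diterpenoid call without OE 67.5 replicate 2 (0.0765).

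**Figure D2:**
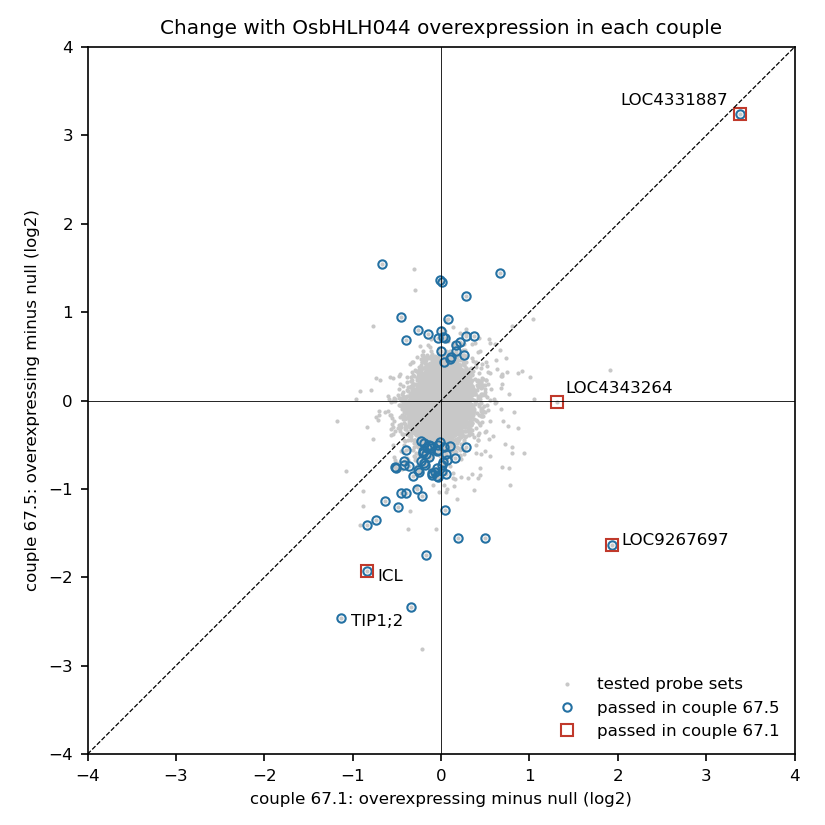
Change in each of the 24251 tested probe sets (overexpressing minus null, log2) in couple 67.1 (horizontal axis) and couple 67.5 (vertical axis); squares mark the 4 probe sets past the threshold in couple 67.1, circles the 83 in couple 67.5, and the dashed line equal change. LOC4331887 lies near the line at 3.38 and 3.24, and LOC9267697 has opposite signs at 1.94 and -1.63.

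Changes shared by the couples were examined next. LOC4331887 rose and ICL fell in both, so 2 genes passed with the same sign, where independent lists would share 0.0031 higher and 0.0024 lower. Whether LOC4331887 measures the transcript of the overexpression construct could not be told. If it does, its rise in both couples is given by the design and is no shared response. LOC9267697 passed in both couples with opposite signs. Of the 83 probe sets that passed in couple 67.5, 61 had the same sign in couple 67.1, or 73.5% against 56.6% of all tested probe sets, and the median ratio of the change in couple 67.1 to that in couple 67.5 was 0.21. Across genes, which are not independent replicates, the changes in the couples correlated with r = 0.191 (Spearman's rho = 0.174). The ICL call in couple 67.1, and with it the shared call, was lost without null 67.1 replicate 1 or 2 or OE 67.1 replicate 1 or 2, which left LOC4331887 as the 1 shared gene. Without OE 67.1 replicate 3 the ICL call was lost too, and another gene passed in both couples in its place.

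The difference between the couples was tested directly, as the change in couple 67.1 minus the change in couple 67.5, and 8 genes passed, 3 higher and 5 lower. LOC9267697 differed by 3.57 (adjusted p = 0.00223): its level was 4.50 ± 0.14 (SD, n = 3) in null 67.1 and 6.44 ± 0.50 in OE 67.1, but 5.70 ± 0.63 in null 67.5 and 4.07 ± 0.35 in OE 67.5. LOC9272344 differed by -2.21 (adjusted p = 6.99e-04), with levels of 5.01 ± 0.14 in null 67.1, 4.34 ± 0.28 in OE 67.1, 4.05 ± 0.24 in null 67.5 and 5.60 ± 0.13 in OE 67.5. The named gene ICL differed by 1.08 (adjusted p = 0.02), as it fell more in couple 67.5, and the remaining differences were 1.32 for LOC4343264, -1.39 for LOC4348634, -1.37 for LOC4329504, -1.33 for LOC9272503 and -1.08 for LOC4349509. TIP1;2 (1.32, adjusted p = 0.455) and CML1 (0.57, adjusted p = 0.992) did not pass this test. Of 33 lists 6 passed, all with positive differences: heat shock, phenylpropanoid, transporter, iron, diterpenoid and photosynthesis genes. None of these calls held with an estimated correlation (smallest adjusted p = 0.315 with an estimated correlation). The calls of LOC9267697, LOC9272344 and LOC4329504 held without each array in turn. LOC4343264 kept its call only without OE 67.1 replicate 1, LOC9272503 only without null 67.5 replicate 1, and LOC4348634 only without OE 67.1 replicate 3 or OE 67.5 replicate 1. ICL kept it only without OE 67.1 replicate 3, null 67.5 replicate 1 or 3 or OE 67.5 replicate 1, and LOC4349509 only without OE 67.1 replicate 2 or 3, null 67.5 replicate 1 or 3 or OE 67.5 replicate 3. The count of 8 fell to 3 without null 67.1 replicate 1, null 67.1 replicate 2 or OE 67.5 replicate 2, to 4 without OE 67.5 replicate 3, and to 5 without null 67.1 replicate 3, OE 67.1 replicate 1, null 67.5 replicate 2 or OE 67.5 replicate 1.

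Finally the null sister lines, neither of which carried the transgene, were compared as a measure of the background between lines. LOC4342250 lay at 3.01 ± 0.12 (SD, n = 3) in null 67.1 and at 9.22 ± 0.14 in null 67.5, a difference of -6.21 (adjusted p = 3.67e-14), and at 2.83 ± 0.11 and 9.11 ± 0.12 in OE 67.1 and OE 67.5. In all 56 probe sets passed, 13 higher and 43 lower in null 67.1. Further genes lower in null 67.1 were LOC4326757 (-1.96), LOC4342552 (-1.51), LOC4328939 (-1.47) and LOC4331398 (-1.21). Of these, LOC4326757 was high in null 67.5 alone (4.98 to 6.77, against 3.34 to 4.09 in the other lines). So was LOC4342552 (4.69 to 5.91, against 3.54 to 4.12). LOC4328939 was higher in both lines of couple 67.5 (6.06 to 6.96, against 4.85 to 5.69). LOC4331398 was low in null 67.1 alone (6.3 to 7.17, against 7.57 to 8.03). Genes that were higher were LOC9271453 (1.08), LOC9271957 (1.03), LOC9272344 (0.96), LOC9267896 (0.92) and LOC9272503 (0.82). Photosynthesis genes were lower in null 67.1 in 17 of 19 cases (adjusted p = 0.00136, and adjusted p = 0.634 with an estimated correlation), 8 of them when adjusted over the list alone, and cytosolic ribosomal proteins in 20 of 21 (adjusted p = 0.00794, and adjusted p = 0.655 with an estimated correlation), none of them when adjusted over the list alone. The number of genes that differed between the null lines depended on single arrays: it was 10 without null 67.1 replicate 1, 12 without null 67.1 replicate 2, 17 without null 67.5 replicate 3, 34 without OE 67.1 replicate 3, 35 without OE 67.5 replicate 2 and 1113 without null 67.5 replicate 1. The array null 67.5 replicate 1 was the only one with a lower mean correlation with its own line (0.9852) than with the other lines (0.9858). It also had the lowest array weight, 0.558. After a further quantile normalization 20 probe sets were higher and 40 lower in null 67.1. With array weights 764 passed, 290 higher and 474 lower, and with the replicate number as a block 507, 157 higher and 350 lower. The calls of LOC4342250, LOC4331398 and LOC9271957 held without each array. LOC4326757 lost its call without any null 67.1 array, LOC4342552 without null 67.1 replicate 1 or 2, LOC4328939 without these or null 67.5 replicate 3, and LOC9272344 without null 67.1 replicate 2 or 3 or null 67.5 replicate 3. LOC9267896 kept it only without null 67.1 replicate 3, null 67.5 replicate 1 or OE 67.5 replicate 3, LOC9271453 only without OE 67.1 replicate 1 or 2 or null 67.5 replicate 1, and LOC9272503 only without null 67.5 replicate 1.

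**Figure D3:**
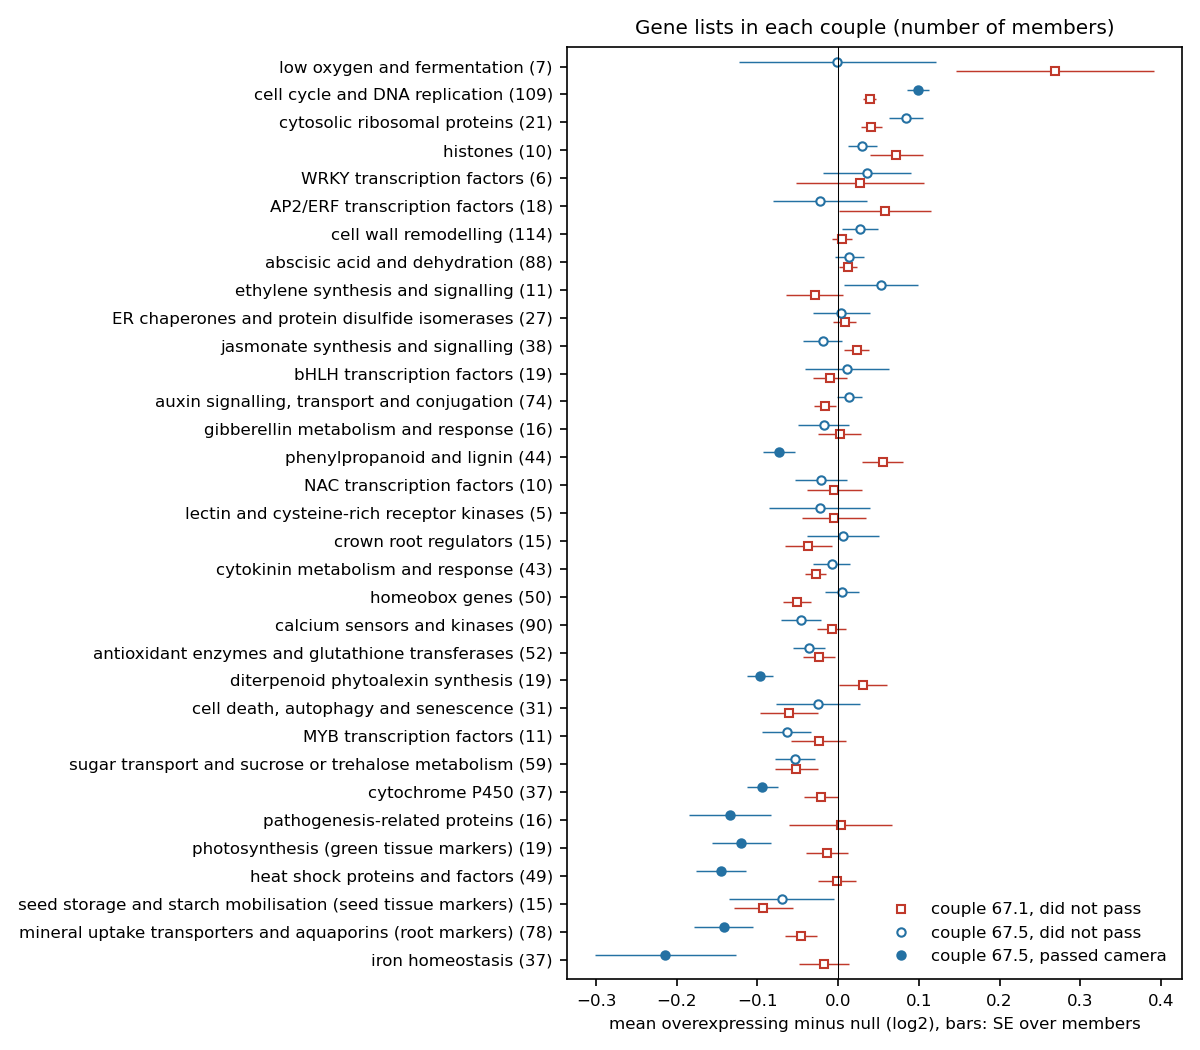
Mean change of each of the 33 tested gene lists (overexpressing minus null, log2; bars, SE over the members) in couple 67.1 (squares) and couple 67.5 (circles), with the number of members in parentheses; filled symbols mark lists past the camera threshold with the preset correlation. No list is filled in couple 67.1, and 9 are filled in couple 67.5.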

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

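The tests of which line stands apart, of single arrays and of a narrower range of values, the test over all probe sets and the comparison of the couples' lines were chosen after the results were seen, and of the others the expectation was written down before the test was run.

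The change with overexpression differed between the couples in 8 genes by the test of the difference itself. The change in couple 67.1 minus that in couple 67.5 was 3.57 for LOC9267697, -2.21 for LOC9272344, -1.39 for LOC4348634, -1.37 for LOC4329504, -1.33 for LOC9272503, 1.32 for LOC4343264, 1.08 for ICL (LOC4343441) and -1.08 for LOC4349509. Of 100 splits of the arrays within the couples, the real one included, 3 gave at least 8 genes. The other splits that did gave 38 and 22 genes, more than the real one. The splits exchange overexpressing and null arrays, so they test for no change with overexpression and not for an equal change in both couples. They therefore cannot exclude chance for this count, and the cause of the difference was not tested.

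By the same test of the difference, 6 gene lists fell less or rose more in couple 67.1. The adjusted p was 0.00136 for heat shock proteins and factors (adjusted p = 0.315 with an estimated correlation), 0.00455 for phenylpropanoid and lignin genes (0.415 with an estimated correlation), 0.0279 for mineral uptake transporters and aquaporins (0.539 with an estimated correlation) and 0.0279 for iron homeostasis (0.49 with an estimated correlation). It was 0.0454 for diterpenoid phytoalexin synthesis (0.539 with an estimated correlation) and 0.0459 for photosynthesis (0.671 with an estimated correlation).

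Couple 67.5 gave 83 calls and couple 67.1 gave 4. A single array as the whole cause is argued against by the lowest count of couple 67.5 without 1 of its arrays, 20, which lay above the highest count of couple 67.1 under any single omission, 6. The spread between arrays was not larger in couple 67.1, as the ratio of the median within-line SDs was 0.885 for couple 67.1 over couple 67.5. All lines share 1 estimate of the spread per gene in this fit, with a median SE of 0.109 in each couple. The SE can therefore not set the counts of the couples apart in this fit, whatever the ratio. It stays open how far the null 67.5 line stands apart. Over the 83 genes the difference between the null lines was a median 0.478 of the change in couple 67.5, with 90.4% in the same direction. In 50 simulations in which OE 67.5 alone changed, the highest values were 0.0562 and 68.4%. Each simulated gene varied on its own, whereas a deviation shared by genes on the null 67.5 arrays would move many ratios together. The simulated values are therefore no bounds for such genes. Whether part of the excess of calls comes from null 67.5 cannot be told from them. A different strength of overexpression in the couples, which the design allows, was not tested.

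The probe sets without a gene in the annotation held some of the largest changes, in data that the comparisons of the report did not use. In the fit over all 36643 probe sets, 10 of these passed on the mean of both couples, 4 higher and 6 lower in the overexpressing lines. Probe set 16362807 rose by 6.71, from 4.32 ± 0.15 (SD, n = 3) to 10.89 ± 0.01 in couple 67.1 and from 3.90 ± 0.07 to 10.74 ± 0.13 in couple 67.5 (adjusted p = 8.56e-14). Probe set 16270679 had a difference of -4.97 (adjusted p = 3.28e-06) and probe set 16342606 of -2.68 (adjusted p = 7.73e-05), and these 3 passed in each couple with the same sign. Their calls on the mean of both couples held without each of the 12 arrays in turn, and those within each couple were not tested in this way.

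The lines of the couples also differed from each other, with or without the transgene. With both lines of couple 67.1 set against both lines of couple 67.5, 3620 probe sets passed, 1509 higher and 2111 lower, and after a second quantile normalization 1257 were higher and 897 lower (5613 in all passed with the replicate number as a block). Of 100 splits of the arrays within the arms only the real one gave as many, 1 split, and the highest other gave 8. Chance in the division of the arrays is therefore excluded. The difference correlated across genes with the mean level (r = -0.333), and the SD of the tested values over an array was 1.37 to 1.44 in couple 67.1 and 1.42 to 1.5 in couple 67.5. A narrower range of values on the arrays of couple 67.1 as the whole cause is argued against by a second quantile normalization, which took the correlation to -0.0522 and left 52.5% of the 3620 calls. The mean of the cytosolic ribosomal list, -0.183, lay just outside the central 95% of random lists matched on level (lower bound -0.182, percentile 2.29), by less than its SE of 0.02, a margin asked for only after the value was seen, so the level of its genes stays open. A difference in genetic background between independent transformants may also contribute to the remaining 52.5% and was not tested.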

How the results depend on the processing

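The test over all probe sets, the omission of the arrays at both ends of the first principal component, and the list tests under other scalings and without single arrays were chosen after the results were seen. No named value reversed its sign under any alternative: over named genes and probe sets 1634 values kept their side of the threshold, 309 lost the call and 11 gained it, and over lists 240 kept it and 32 lost it. Many of the 1634 belong to genes that did not pass in the main fit and so had no call to lose. Set against them, the 309 losses understate how often a call was lost.

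On the mean of both couples, 45 became 13 with 6 against 6 arrays, 6 with a log2 difference of at least 1, 25 over all probe sets and 9 without both end arrays (null 67.1 replicate 1 and OE 67.5 replicate 3). Couple 67.1 gave 7 in place of 4 with the low-value filter, quantile normalization, eBayes with trend and robust, or array weights, and 2 without both end arrays. Couple 67.5 gave 29 in place of 83 with only the 6 arrays of the couple, 22 with a log2 difference of at least 1, 33 over all probe sets and 21 without both end arrays. The difference between couples gave 5 in place of 8 after quantile normalization and 1 without both end arrays. The null lines gave 764 in place of 56 with array weights, 14 with a log2 difference of at least 1 and 4 without both end arrays. Genes changed in both couples were 1 in place of 2 with a log2 difference of at least 1, 5 over all probe sets and 1 without both end arrays. Of the 7 lists 0 passed with an estimated correlation, where 2183 of the tested probe sets had an unadjusted p under 0.05. A stricter threshold lowers a count by construction. For the other changes, some of which raised a count, the cause was not tested.

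Leaving out each array in turn gave 14 to 46 for the mean of both couples, 2 to 6 for couple 67.1, 20 to 88 for couple 67.5, 3 to 7 for the difference between couples, 10 to 1113 for the null lines, 1 to 3 for genes changed in both couples and 5 to 11 for the lists. The replicate number is not stated to mark a shared day, and 11 of 18 same-numbered pairs of arrays deviated together with a correlation over 0.1 (range -0.25 to 0.42), while 7 of 12 arrays correlated best with an array of their own number. All pairs numbered 3 correlated by 0.16 to 0.42, against -0.06 to 0.29 for pairs numbered 1 and -0.25 to 0.24 for pairs numbered 2. Replicate 3 also had the highest value of its line on the first principal component in every line. The main fit does not model such a shared deviation. With the replicate number as a block the null lines gave 507 in place of 56, the overexpressing lines 2048 in place of 201 and the lines of the couples 5613 in place of 3620, while the other counts moved by at most 1.5 times. After quantile normalization the overexpressing lines and the lines of the couples gave 61 and 2154. Quantile normalization and median centring moved the median of all tested probe sets by at most 0.0254. Not run were the omission of probe sets by name suffix, since the names carry none, and the levels of OsbHLH044 and CRL1.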

Other observations

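The comparison of the couples' lines and the tests on probe sets without a gene, on neighbouring genes, on the largest risers and on lists matched on level were chosen after the results were seen, and for the splits the expectation was written down before they were run.

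Gene groups were compared between the couples with the overexpressing and null lines pooled. Of the null lines alone 2 lists passed and of the overexpressing lines alone 9, so the differences below are not shown to be independent of the transgene, and none of them passed with an estimated correlation. In both lines of couple 67.1 together, compared with both lines of couple 67.5, diterpenoid phytoalexin genes were higher in 18 of 19 cases (adjusted p = 0.00139, and adjusted p = 0.371 with an estimated correlation) and pathogenesis-related proteins in 12 of 16 (adjusted p = 0.0106, and adjusted p = 0.371 with an estimated correlation). AP2/ERF factors were higher in 15 of 18 cases (adjusted p = 0.0314) and cytochrome P450 genes in 28 of 37 (adjusted p = 0.0258), both with adjusted p = 0.371 with an estimated correlation. Genes of cell death, autophagy and senescence were lower in 25 of 31 cases (adjusted p = 0.00856, and adjusted p = 0.521 with an estimated correlation), cell cycle genes in 87 of 109 (adjusted p = 0.00139, and adjusted p = 0.596 with an estimated correlation) and cytosolic ribosomal proteins in 19 of 21 (adjusted p = 0.00139, and adjusted p = 0.596 with an estimated correlation). Photosynthesis genes were lower in 17 of 19 cases (adjusted p = 0.0109) and ER chaperones in 21 of 27 (adjusted p = 0.0303), both with adjusted p = 0.588 with an estimated correlation. Among the overexpressing lines alone, 201 probe sets passed, 77 higher and 124 lower in OE 67.1. After a second quantile normalization 61 passed, 29 higher and 32 lower, and with the replicate number as a block 2048 passed.

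Among probe sets without a gene, 16122868 was 3.32 higher in null 67.1 than in null 67.5 (adjusted p = 1.41e-07) and 16352755 differed by -3.09 (adjusted p = 0.00228). Probe set 16165683 rose by 2.11 in couple 67.5 (adjusted p = 1.54e-04) and differed by 0.11 in couple 67.1, and the difference between couples was -1.99 (adjusted p = 0.0222).

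Other splits of the arrays can exclude chance in the division of the arrays for some of the counts. Each arm of a couple is 1 line, so these splits cannot separate the transgene from other differences between sister lines. For the mean of both couples 1 of 100 splits within the couples, the real one, gave at least 45 probe sets, and the highest other gave 38. For genes changed in both couples 1 of 100 gave at least 2, and the highest other gave 0. For gene lists 8 of 100 splits gave at least 7 lists and the highest other gave 10, so chance cannot be excluded for the number of lists. The 10 splits of 6 arrays are too few for a share under 0.05: couple 67.1 gave 4 probe sets in the real split and 6 in the highest other, with 2 of 10 at least as high as the real one. Couple 67.5 gave 83 and 0, the null lines 56 and 2, and the overexpressing lines compared with each other 201 and 1, with 1 of 10 splits at least as high in each.

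A hypothesis was that 1 of the largest risers measures the transcript of the overexpression construct. In each couple alike 2 of the 36643 probe sets rose by over 3, LOC4331887 and the unnamed probe set 16362807. Neither carries the name of OsbHLH044 in the annotation used, and with 2 risers of this kind the values cannot show whether either may be that transcript.

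Another hypothesis was that genes near each other on the chromosomes changed together, since TIP1;2 (LOC4324303) and its neighbour LOC4324302 both fell in couple 67.5, with differences of -2.45 and -0.77. The call of LOC4324302 was lost without OE 67.5 replicate 1 or 3. Of 137 genes that passed in any of the 5 comparisons, 9 had another within 5 measured genes, against a mean of 7.59 and a 95% range of 2 to 16 in 10000 random sets matched on level (permutation test with these random sets, p = 0.34, adjusted over 4 sets 0.45). On the mean of both couples the number was 4, against a mean of 0.819 and a range of 0 to 4 (p = 0.06 and adjusted p = 0.24 in the same permutation test). In couple 67.5 it was 6 against 2.79 (0 to 8, permutation p = 0.16) and between the null lines 0 against 1.27 (0 to 5). All lay within the range of random sets, the mean of both couples at its upper end. Of 3 neighbouring pairs that passed in the same comparison, 1 changed in opposite directions, LOC4334969 and LOC4334970 (0.72 and -1.08 in couple 67.5), and 3 pairs are too few to tell whether probe sets of near-identical neighbours share a transcript.

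Lists were also set against 10000 random lists of the same size matched on mean level, since the change on the mean of both couples correlated with level across genes (r = 0.141). The mean of the transporter list (-0.09) lay below the central 95% of random lists (-0.03 to 0.03), as did those of the iron (-0.12) and heat shock (-0.07) lists, and that of the cell cycle list (0.07) lay above it (-0.01 to 0.04). The means of the cytochrome P450 (-0.06), photosynthesis (-0.07) and sugar (-0.05) lists lay below it too. These 7 lists passed in camera, with an adjusted p of 0.0972 to 0.565 with an estimated correlation. Lists that did not pass in camera also lay outside this range: pathogenesis-related proteins (-0.065), cell death (-0.04), antioxidant enzymes (-0.03), seed tissue markers (-0.08) and calcium sensors (-0.03) below it, and low oxygen genes (0.13) above it. Lying outside this range is therefore no evidence for a list on its own.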
